A study of Danio rerio with 5 samples.

How the data were processed

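Total RNA of whole zebrafish embryos at 14 h post fertilization was hybridised to 5 arrays, 3 of embryos injected with control morpholino and 2 of embryos injected with gata5 and gata6 morpholinos, as the sample labels state. Per the labels, RNA was extracted with TRIzol, cleaned on columns with DNase, and amplified and labelled with Cy3 in a 1-colour kit. Per the file headers, the arrays were read with Agilent Feature Extraction version 10.7.3.1, whereas the submitters' processing notes name version 10.7.1.1. Per the file headers, the deposited processed signal of each spot is an intensity that was background-subtracted and detrended within the array, with low values replaced by a surrogate, and it was not scaled between arrays. The deposited files also hold the raw median intensity of each spot and of its local background, and marks for spots well above background, saturated or non-uniform. The deposited value table of the series holds log2 values of the same arrays, with medians of 6.10. Its columns share a common distribution, as quantile normalization gives, since over its 43663 rows the values at equal rank differed by at most 0.000844 between columns, and they correlated with the log2 signals used here at 0.9998 to 1.000 across probes. The method by which the authors made that table is not given in the sources used here. Its scale is log2 by this comparison, its values are not centred on 0, and direction does not apply to 1-colour values.

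Each array held 43803 non-control spots of 43603 probes. The log2 of the processed signal was reduced by the log2 of the array's 75th percentile, which ranged from 506 to 574 intensity units, and spots of a probe were averaged on the log2 scale. Control spots were left out, as were 52 probes with an outlier spot on any array. A probe was kept if it was well above background on every array of at least 1 group, which left 30618 probes. Probes carry accessions, which were matched without versions to the RefSeq gene table of assembly GRCz12tu for names alone. A symbol was found for 25598 probes (58.7%), making 13143 symbols, and 18005 probes had none. The array was designed on another genome build, so no coordinates are given. A gene was represented by its brightest probe on average, which gave 10792 genes, of which 6142 had more than 1 probe, and probes of 6 genes passed the test in opposite directions.

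Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates, 3 residual degrees of freedom), and a gene passed at a two-sided Benjamini-Hochberg adjusted p under 0.05. The words rose, fell, higher and lower refer to the gata5/6 morpholino group relative to the control group. Where a gene was not well above background on any array of a group, its level there is a bound. The fold is then given as at least N-fold, from the brighter group's mean against the dim group's mean of, per array, the higher of the probe's signal and the lowest signal among probes well above background. The fitted log2 change of such a gene is not a bound. Shifts of 20 gene lists against all other genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 20 lists. Its calls for the cardiac, p53 and myeloid lists were lost with a correlation estimated for each list, which leaves no list passing. Camera with an estimated correlation uses only the 3 residual degrees of freedom, whereas the preset form uses many more. It therefore has little power here, and a call lost there need not come from correlation among members. The fry test, which asks whether a list's genes move on balance in 1 direction, was an alternative. The median of a list was positive while camera leaned lower for lateral plate mesoderm, endoderm, neural tissue, neural crest and cell cycle, and the mean was negative for the first, second and last of these. Gene names in the lists were updated through the same table, so that vmhc appears as myh7.

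The gene lists, the tests and the rule for naming genes were fixed before the data were examined. The rule named gata4, gata5 and gata6, then the 12 largest rises and 12 largest falls by fitted log2 change. The rises and falls were taken among genes that passed and had both gata5/6 morpholino arrays beyond all control arrays, leaving out placeholder names. Genes not well above background in 1 group were thus ranked on fitted values that are not bounds. Of the 12 largest falls, 1 is not reported here, and it stays in all counts. It also named the 4 measured members of each list with the smallest adjusted p. Other genes are said to have been chosen after their values were seen. The alternatives were normexp background correction (offset 50, on the median signal since the files hold no mean signal), quantile normalization, the authors' value table, no filter on dim probes, only probes above background on all 5 arrays, and the mean over a gene's probes. Further alternatives were eBayes with trend and robust settings, the replicate number as a block, a 2-fold minimum, probes in place of genes, and leaving out each array in turn. A normexp fit with spots below their background repaired, a variance for each group and 3 further gene lists were chosen after seeing the data. The slide could not be fitted as a block because each slide held 1 group.

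The procedure was tested on simulated data for this comparison with 10792 genes and 20 runs. It recovered 24.5% of genes changed by a log2 of 0.5, 67.6% of those changed by 1 and 93.7% of those changed by 2, and 4.31% of its calls were unchanged genes. Camera passed a list of 20 genes shifted by a log2 of 0.5 in 20 of 20 runs and a list of 20 unchanged genes in 0 of 20. The simulation gave each gene 1 spread on all 5 arrays and made genes independent. In the data the gata5/6 morpholino arrays had the larger spread (median SD 0.170 against 0.0654), and members of the p53 list had an estimated correlation of 0.474. These rates therefore need not hold for the data.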

Results

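Zebrafish (Danio rerio) embryos were injected at the 1-cell stage with morpholinos, short synthetic oligonucleotides that pair with a chosen RNA and block its translation or splicing. Whole embryos were collected at 14 h post fertilization, and their total RNA was measured on 1-colour Agilent arrays. The control group (3 arrays) received 7.5 ng of control morpholino per embryo, and the gata5/6 morpholino group (2 arrays) received 6.25 ng against gata5 together with 1.25 ng against gata6. The gata4, gata5 and gata6 genes encode zinc-finger transcription factors of the heart and gut. Per the labels, this pair of morpholinos has been reported to lower gata4 as well, and the comparison asked which genes change when all 3 factors are reduced. On each array 70.1% to 71.1% of the 43603 probes were well above background, and no spot was saturated. The number of arrays limits the precision of every value, and the labels do not say that replicates came from separate clutches, so p-values measure the spread between these samples, which may be technical. All 3 control arrays lay on slide 1 and scan 1 and both gata5/6 morpholino arrays on slide 2 and scan 2, so batch and group cannot be told apart.

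The targeted genes did not move alike. The gata4 signal was lower in the gata5/6 morpholino embryos, with a mean log2 signal of -1.96 ± 0.05 (SD, n = 2) against -1.32 ± 0.03 (SD, n = 3) in controls, a log2 change of -0.64 (limma, SE 0.0812, adjusted p = 0.00520). The gata5 signal was 3.95-fold higher (log2 change 1.98, SE 0.0988, adjusted p = 0.000191), and the other probe of the gene gave a log2 change of 2.38. The gata6 signal was 7.21-fold higher (log2 change 2.85, SE 0.0893, adjusted p = 5.76e-05), and its 3 probes gave 2.73 to 2.89. Both gata5/6 morpholino arrays lay beyond all 3 control arrays for each of these genes. A morpholino can block translation without lowering its target's RNA, and the labels do not say which step was blocked, so the gata5 and gata6 RNA levels do not check the injection. The other GATA factors measured were gata2a (log2 change -0.42, adjusted p = 0.112), gata3 (-0.41, adjusted p = 0.191) and gata1a (0.21, adjusted p = 0.232). None of these 3 passed over all genes or adjusted over the list alone, where 1 had an unadjusted p under 0.05, and their list gave a camera adjusted p of 0.631. All 3 targeted genes passed adjusted over the list alone, and their list, with 2 risen and 1 fallen, had a camera adjusted p of 0.190.

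The heart genes nkx2.5 and tnnt2a were among the 12 largest falls by fitted change after gata5/6 morpholino. The cardiac transcription factor gene nkx2.5 was at least 7.53-fold higher in control embryos (adjusted p = 0.000103), and it was not well above background on either gata5/6 morpholino array. The gene of cardiac troponin T, tnnt2a, which the sarcomere needs to contract, was 9.95-fold lower (log2 change -3.31, SE 0.146, adjusted p = 0.000135). The T-box factor gene tbx20 was at least 2.61-fold higher in controls (adjusted p = 0.00160), and nppa, which encodes natriuretic peptide A, at least 1.53-fold (adjusted p = 0.00103), a call lost with the repaired normexp fit, chosen after seeing the data (log2 change -0.22, adjusted p = 0.141). Of the 16 measured genes of cardiac progenitors and cardiomyocytes, 9 fell, 2 rose and 5 did not pass. The same 11 genes passed adjusted over the list alone. The following members were chosen after their values were seen. The factor gene hand2 was 2.15-fold lower (adjusted p = 0.00273), and the ventricular myosin gene myh7, listed under its older name vmhc, was at least 1.48-fold higher in controls (adjusted p = 0.00164). The MEF2 factor genes parted, with mef2ca at -0.90 (adjusted p = 0.0106) and mef2cb at 0.76 (adjusted p = 0.00319). The gene of hyaluronan synthase 2, has2, rose with a log2 change of 0.80 (adjusted p = 0.00300). Early factor genes that did not pass were nkx2.7 (-0.15, adjusted p = 0.366), isl1a (-0.12, adjusted p = 0.404) and bmp4 (-0.10, adjusted p = 0.461). The median log2 change of the list was -1.01, or -0.59 with its 6 members that were not well above background in 1 group placed at their bounds, -0.66 with default normexp and -0.21 with repaired normexp. Both normexp fits add an offset of 50, which by construction shrinks log2 changes of dim genes such as nppa toward 0. By camera the list was lower than other genes (adjusted p = 8.58e-05). With a correlation estimated from the data, on only the 3 residual degrees of freedom, this call was lost (adjusted p = 0.349 with an estimated correlation). That correlation, -0.0554, was below the preset 0.01. The call was also lost over probes well above background on all 5 arrays, where the median was -0.13 (camera adjusted p = 0.219). That filter removes the genes that fell below background.

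**Figure D1:**
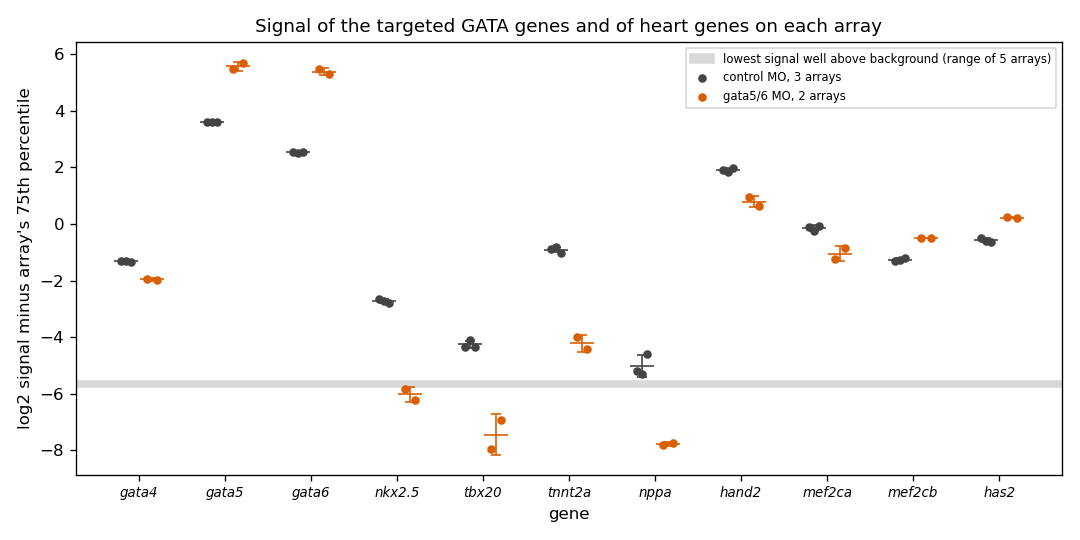
Normalized log2 signal, relative to the 75th percentile of each array, of the 3 targeted genes and 8 heart genes. Points are arrays (3 control, 2 gata5/6 morpholino), lines are means ± SD, and the grey band spans the lowest signals well above background on the 5 arrays, which nkx2.5, tbx20 and nppa do not reach after gata5/6 morpholino, while gata5 and gata6 lie 1.98 and 2.85 above their control means.

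Across the embryo, 846 genes were higher and 774 lower in the gata5/6 morpholino group among 10792 genes tested (limma, Benjamini-Hochberg adjusted p under 0.05). For all 1620, both gata5/6 morpholino arrays lay on the same side of all 3 control arrays. Passing with so few arrays nearly requires this, so it is not separate evidence. By fitted change, 290 of the higher and 217 of the lower genes changed at least 2-fold and 109 and 56 at least 4-fold. With the 129 genes that passed but were not well above background in 1 group placed at their bounds, these counts were 266 and 197, and 82 and 41. The median log2 change of all genes tested was 0.04. The gata5/6 morpholino arrays differed more from each other (median SD per gene 0.170) than the control arrays did (0.0654). Without 1 array the counts of higher and lower genes were 423 and 339 (control replicate 1), 377 and 364 (control replicate 2), 371 and 314 (control replicate 3), 956 and 1055 (gata5/6 morpholino replicate 1) or 3114 and 2166 (gata5/6 morpholino replicate 2). They were 290 and 257 when each group had its own variance, an alternative chosen after seeing the data, and 19 and 23 with a default normexp background correction.

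Among the 12 largest rises, the genes leg1.1 and leg1.2, which encode secreted liver-enriched proteins and are close copies that the probes may not tell apart, were 19.2-fold (log2 change 4.26, SE 0.199, adjusted p = 0.000162) and 18.1-fold higher (4.18, SE 0.104, adjusted p = 4.11e-05). The fetuin gene ahsg1 was 17.4-fold higher (4.12, SE 0.207, adjusted p = 0.000197), with 2.84 and 3.25 from its other probes and 3.24 from the other leg1.2 probe, and urad, which encodes an enzyme of urate breakdown, was 19.5-fold higher (4.29, SE 0.208, adjusted p = 0.000180). The neurofilament gene nefmb was 16.0-fold higher (SE 0.193 on the log2 scale, adjusted p = 0.000177). The glucuronosyltransferase genes ugt1a7 and ugt1a1, also related copies, were 15.6-fold and at least 8.22-fold higher (adjusted p = 0.000220 and 0.00261), and the second of these calls was lost when each group had its own variance (adjusted p = 0.0841). The rest of these rises were in genes not well above background on any control array. These were the aldo-keto reductase gene akr1a1a (at least 17.2-fold, adjusted p = 8.52e-05), the cytochrome P450 gene cyp2ad2 (at least 7.97-fold, adjusted p = 0.00135) and the immune-type receptor gene nitr8 (at least 6.69-fold, adjusted p = 0.000180). The phosphate transporter gene slc20a1a (at least 4.54-fold, adjusted p = 0.000472) and the ribonuclease-like gene rnasel2 (at least 3.51-fold, adjusted p = 5.76e-05) were higher too.

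Among the largest falls, the gene of the fatty acid receptor CD36, cd36, was 52.2-fold lower after gata5/6 morpholino (log2 change -5.70, SE 0.128, adjusted p = 4.11e-05). The apolipoprotein genes apoa4a and apoea were 15.2-fold and 13.2-fold lower (adjusted p = 0.000357 and 0.00166), the other apoa4a probe gave a log2 change of -3.30, and apoea was well above background on 1 of the 2 gata5/6 morpholino arrays. The gene epd, which encodes the secreted glycoprotein ependymin, was at least 26.5-fold higher in controls (adjusted p = 4.11e-05). The cytochrome P450 gene cyp1c1 was 16.0-fold lower (log2 change -4.00, SE 0.156, adjusted p = 0.000103), and the glucose transporter gene slc2a3a was 9.58-fold lower (-3.26, SE 0.0906, adjusted p = 4.11e-05). The repressor gene bhlhe41 was at least 9.64-fold higher in controls (adjusted p = 0.000623), the phosducin gene pdcb at least 3.81-fold (adjusted p = 0.000165), and the peptide receptor gene prlh2r at least 2.92-fold (adjusted p = 0.000181). The ranks of epd, bhlhe41, pdcb and prlh2r rest on fitted changes. The bounds of epd and bhlhe41 still exceed the fold of slc2a3a, the smallest of the 12 fitted falls. The bounds of pdcb and prlh2r alone might not place them among the largest falls.

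Of the 15 measured genes of the p53 response, which follow DNA damage and other cell stress, 10 fell, none rose and 5 did not pass, with a median log2 change of -0.75, and 10 passed adjusted over the list alone. By camera the list was lower than other genes (adjusted p = 6.81e-07), and this call was lost with a correlation estimated from the data (adjusted p = 0.612 with an estimated correlation). The gene of the p53 inhibitor, mdm2, was 2.16-fold lower (log2 change -1.11, SE 0.123, adjusted p = 0.00328). The pro-apoptotic genes bbc3 and casp8 were 2.11-fold and 2.45-fold lower (adjusted p = 0.00271 and 0.00279). The gene isg15, which also answers to interferon, was 4.29-fold lower (log2 change -2.10, SE 0.222, adjusted p = 0.00275). When each group had its own variance, the calls of mdm2, casp8 and isg15 were lost, at adjusted p of 0.0565, 0.0530 and 0.0530.

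Blood and vessel genes moved in different directions. The gene spi1b, which encodes a factor that directs myeloid cells, was 4.33-fold lower (log2 change -2.11, SE 0.105, adjusted p = 0.000188), and the macrophage factor gene irf8 was 2.66-fold lower (-1.41, SE 0.0914, adjusted p = 0.000502). Of the 12 measured genes of primitive myeloid cells, 5 fell, none rose and 7 did not pass (7 passed adjusted over the list alone, 1 higher and 6 lower), with a median of -0.31. The remaining named members were rac2 (-0.60, adjusted p = 0.0101) and mmp9 (-0.43, adjusted p = 0.0243), both of which lost their calls without control replicate 1, 2 or 3 (rac2 -0.58 to -0.61, mmp9 -0.40 to -0.45), mmp9 also with the replicate block (adjusted p = 0.106). The list was lower than other genes by camera (adjusted p = 0.0442), but with an adjusted p = 0.597 with an estimated correlation, 0.0543 with quantile normalization and 0.0531 from the authors' values. The call was also lost without control replicate 2 (median -0.31, adjusted p = 0.0541), gata5/6 morpholino replicate 1 (-0.39, 0.106) or replicate 2 (-0.23, 0.178), with no filter on dim probes (-0.13, 0.131) and over probes above background on all 5 arrays (-0.31, 0.0526). Among endothelial and angioblast genes, 4 of 12 rose, 1 fell and 7 did not pass (6 passed adjusted over the list alone, median 0.23, camera adjusted p = 0.177). The gene that fell was the VEGF receptor gene kdr, at 4.92-fold lower (log2 change -2.30, SE 0.0860, adjusted p = 9.44e-05), with -3.63 and -2.46 from its other probes. The related gene kdrl, chosen after its value was seen, did not pass (log2 change 0.02, adjusted p = 0.952). The cadherin gene cdh5 was at least 1.78-fold higher than in controls, where it was not well above background (adjusted p = 0.00456), but its log2 change was -0.29 with the default normexp correction and its call was lost when each group had its own variance (adjusted p = 0.109). The angioblast factor gene etsrp rose with a log2 change of 0.52 (adjusted p = 0.0124) and clec14a with 0.69 (adjusted p = 0.0245), and both calls were lost without control replicate 1, 2 or 3 (0.49 to 0.54 and 0.65 to 0.75). Of 14 primitive erythroid genes, 2 rose and 12 did not pass, and the same number passed adjusted over the list alone (median 0.07, camera adjusted p = 0.432). These were the globin genes hbae1.1 (0.61, adjusted p = 0.0118) and hbbe2 (0.88, adjusted p = 0.0376), members of families of near-identical copies and therefore uncertain. With a variance for each group, etsrp, clec14a, hbae1.1, hbbe2, rac2 and mmp9 lost their calls (adjusted p of 0.0532 to 0.228). The hbae1.1 call was lost without control replicate 1, 2 or 3 (0.57 to 0.64). The hbbe2 call was lost without control replicate 2, control replicate 3 or gata5/6 morpholino replicate 1 (0.62 to 0.86), with no filter on dim probes (adjusted p = 0.0723) or with the mean over probes (0.0695), and its log2 change was -0.12 with the default normexp correction. With the repaired normexp fit the cdh5 and hbbe2 calls held.

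Among other mesoderm lists, the lateral plate signal gene bmp16 was 3.48-fold lower (log2 change -1.80, SE 0.128, adjusted p = 0.000716), although well above background on 1 of the 2 gata5/6 morpholino arrays, and fgf10a was 1.66-fold lower (-0.73, adjusted p = 0.00790), while the forkhead genes foxf1 and foxf2a were 2.23-fold and 1.59-fold higher (adjusted p = 0.00498 and 0.00641). The foxf2a log2 change was -0.16 with the default normexp correction, although its call held with the repaired normexp fit. The calls of foxf2a and fgf10a were lost when each group had its own variance (adjusted p = 0.0721 and 0.0796). Of the 8 measured genes of lateral plate mesoderm outside the heart, 3 rose, 3 fell and 2 did not pass (6 adjusted over the list alone, median 0.06, camera adjusted p = 0.952). Among genes of the pronephros, the embryonic kidney, cdh17 was 5.06-fold higher in whole embryos (log2 change 2.34, SE 0.110, adjusted p = 0.000165) and the podocyte factor gene wt1a was 2.77-fold lower (-1.47, SE 0.151, adjusted p = 0.00249). The nephron genes lhx1a (-0.68, adjusted p = 0.0107) and slc4a4a (-0.63, adjusted p = 0.0153) were also lower. Each lost its call without control replicate 1 (-0.64 and -0.58), lhx1a also without control replicate 2 (-0.66) and slc4a4a without control replicate 3 (-0.62), and both with a variance for each group (adjusted p = 0.0782 and 0.158). Of the 7 measured genes of pronephros and intermediate mesoderm, 4 fell, 1 rose and 2 did not pass (5 adjusted over the list alone, median -0.56, camera adjusted p = 0.0860). Of the 10 genes of cranial and pharyngeal mesoderm, 1 rose, 1 fell and 8 did not pass (2 adjusted over the list alone, median -0.05, camera adjusted p = 0.709). The gene that fell was tcf21 (-0.84, adjusted p = 0.0139), a head muscle factor gene, whose call was lost without control replicate 2 (-0.84) or 3 (-0.77) and which was well above background on 1 of the 2 gata5/6 morpholino arrays. The gene that rose was six1a (0.47, adjusted p = 0.0222), whose call was lost without control replicate 1, 2 or 3 (0.42 to 0.50) and with the replicate block (adjusted p = 0.0867). With a variance for each group, tcf21 (adjusted p = 0.0918) and six1a (0.180) lost their calls, and tcf21 also with repaired normexp (-0.11).

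Endoderm genes also moved both ways. The genes prdx5 and onecut1 were 2.63-fold and 2.71-fold lower (adjusted p = 0.00174 and 0.00440), and the factor genes hhex and mnx1 were 1.46-fold and 1.47-fold higher (adjusted p = 0.00882 and 0.00959). The hhex and mnx1 calls were lost without control replicate 1, 2 or 3 (log2 change 0.54 to 0.58) and with a variance for each group (adjusted p = 0.0570 and 0.0647). Of the 17 measured genes of endoderm and early gut, 4 rose, 3 fell and 10 did not pass (9 adjusted over the list alone, median 0.07, camera adjusted p = 0.901). Of 8 genes of pharyngeal endoderm, 1 fell and 7 did not pass (1 adjusted over the list alone, median -0.12, camera adjusted p = 0.455). That gene was pax1a (-0.58, adjusted p = 0.0160), whose call was lost without control replicate 1 (-0.56) or 2 (-0.55), with a variance for each group (adjusted p = 0.133) and with repaired normexp (-0.11). Of 16 genes of gastrula stages, 3 rose, 1 fell and 12 did not pass (5 adjusted over the list alone, median 0.12, camera adjusted p = 0.455). They were mixl1 (1.00, adjusted p = 0.00494), nog1 (0.61, adjusted p = 0.00616), sox32 (1.66, adjusted p = 0.0435), a factor gene that specifies endoderm and is also on the endoderm list, and tdgf1 (-0.91, adjusted p = 0.00779). The sox32 call was lost without control replicate 2 (1.33), control replicate 3 (1.58), gata5/6 morpholino replicate 1 (1.61) or replicate 2 (1.70), and the nog1 call without control replicate 3 (0.59). When each group had its own variance, mixl1 (adjusted p = 0.0835) and sox32 (0.389) lost their calls, and sox32 also with no filter on dim probes (0.0850).

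Few genes of the remaining tissues passed. Among 19 genes of somites and skeletal muscle, pvalb2, a parvalbumin gene, was 3.68-fold higher (log2 change 1.88, SE 0.165, adjusted p = 0.00137) and 18 did not pass (1 adjusted over the list alone, median 0.05, camera adjusted p = 0.677). Of 19 neural genes only en2a, of the midbrain-hindbrain boundary, passed (0.47, adjusted p = 0.0329, list median 0.02, camera adjusted p = 0.952), and of 11 neural crest genes only dlx2a (-0.56, adjusted p = 0.0378, list median 0.09, camera adjusted p = 0.952). Of 16 epidermis and ionocyte genes only tp63 passed (-0.47, adjusted p = 0.0491, list median -0.03, camera adjusted p = 0.705). Of 17 genes of retinoic acid metabolism and response only cyp26a1, which encodes an enzyme that degrades retinoic acid, passed (-0.39, adjusted p = 0.0377, list median -0.12, camera adjusted p = 0.0860). Adjusted over the list alone, 0 genes of these 4 lists passed. Each of these 4 calls was lost with a variance for each group (adjusted p of 0.135 to 0.255) and without control replicate 1, 2 or 3 (en2a 0.40 to 0.52, dlx2a -0.48 to -0.63, tp63 -0.45 to -0.48, cyp26a1 -0.38 to -0.42), and those of en2a (0.49) and dlx2a (-0.43) also without gata5/6 morpholino replicate 1. With no filter on dim probes all 4 were lost (adjusted p of 0.0542 to 0.0808), as were those of tp63 and cyp26a1 with the mean over probes (0.115 and 0.0526) and the replicate block (0.0627 and 0.0887), and that of tp63 with quantile normalization (0.0518) and the authors' values (0.0528). In limma's test, 0 of 14 genes of notochord, floor plate and hatching gland passed, over all genes or adjusted over the list alone (median -0.03, camera adjusted p = 0.455), and 0 of 15 cell cycle genes (median 0.09, camera adjusted p = 0.952). At an unadjusted p under 0.05 there were 4 genes in each of these lists, led by col9a2 (log2 change -0.29, adjusted p = 0.0869) and plk1 (-0.27, adjusted p = 0.0808).

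**Figure D2:**
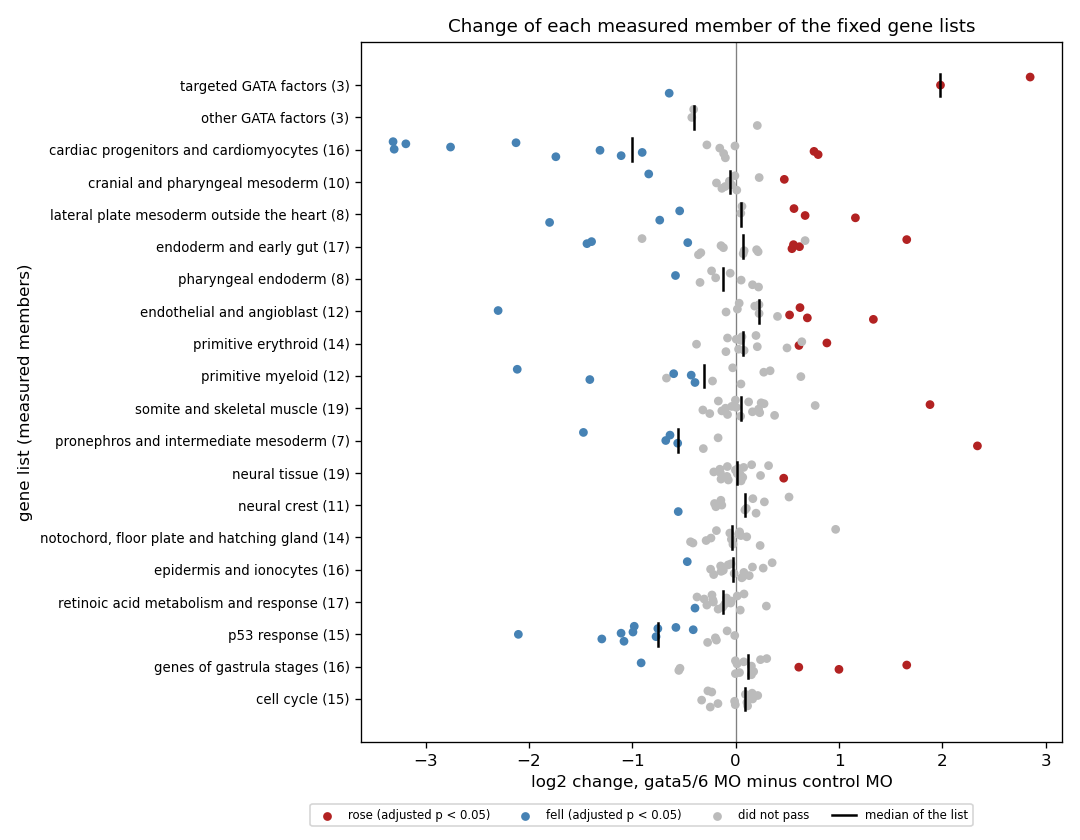
Log2 change (gata5/6 morpholino minus control) of each measured member of the 20 gene lists, with the number of measured members in parentheses. Each point is a gene, coloured by whether it rose, fell or did not pass at an adjusted p of 0.05, and bars are list medians, which lie at -1.01 for the cardiac list, -0.75 for the p53 list and 0.05 for the muscle list.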

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

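The test of probes without a gene symbol was chosen after the data were seen. Of 10120 such probes that passed the filter on dim probes, 660 were higher and 633 lower after gata5/6 morpholino (limma, adjusted p under 0.05). They stand out because no comparison of named genes uses them, and they are given as values only.

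The 1620 genes that passed differed between 2 groups that lay on separate slides. A difference in signal between slides or scans was tested on control probes for spiked-in RNA. Of the 8 such probes above background on all arrays, the one that differed most did so by 0.112 (log2). This was below the bound of 0.5 set for it and below the smallest change among genes that passed (0.31). The signals of these probes had been scaled to each array in the same way as those of the genes. A signal difference common to a slide was thus removed beforehand, and the test could not show it. These 8 probes also do not speak for slide or scan differences limited to other probes, so a slide or scan difference stays open. A difference in embryo clutch, RNA preparation or labelling between the groups stays open, since 0 slides held both groups, and it cannot be told apart from the morpholinos for any of these genes. The knockdown itself also stays open, as the difference that the design names.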

How the results depend on the processing

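The normexp fit with repaired spots and the variance for each group were chosen after seeing the data. Counts of 846 higher and 774 lower genes stayed within 1.5 times under quantile normalization (837 and 832, 96.1% of the calls kept), the authors' table (843 and 824, 96.2%), both other filters on dim probes, the mean over probes, eBayes with trend and robust settings, and the repaired normexp fit (908 and 715, 81.4%). They were 290 and 217 with a 2-fold minimum and 1862 and 1723 over probes, by construction. They were 290 and 257 (33.8% of the calls kept) with a variance for each group, where the gata5/6 morpholino arrays had the larger spread (median SD 0.170 against 0.0654). Leaving out 1 array gave 371 to 3114 higher and 314 to 2166 lower genes from fewer arrays, and a lone gata5/6 morpholino array is then assumed to vary like the controls. Default normexp gave 19 and 23. There, 5 spots of control replicate 3 lay below their local background, by up to -11992.5, and the lowest 1% of its corrected signals was 322 against 55.4 to 66.3 on the other arrays. Default normexp turned foxf2a (-0.16), cdh5 (-0.29) and hbbe2 (-0.12), and 53 named genes lost their calls. With the repaired fit these reversals were absent, and the named genes that lost their calls were nppa, tcf21 and pax1a. Both fits add an offset of 50, which shrinks changes of dim genes, so smaller changes there need not come from the background correction.

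The p53 list lost its call with an estimated correlation alone (median -0.75, adjusted p 0.612, camera range over alternatives 3.42e-09 to 0.612). The cardiac list lost it there (-1.01, 0.349, range 5.94e-12 to 0.349) and over probes above background on all 5 arrays (-0.13), which removes genes that fell below background, and its median was -0.66 with default and -0.21 with repaired normexp. The myeloid list lost it with quantile normalization (-0.33), the authors' table (-0.33), no filter (-0.13), probes above background on all 5 arrays (-0.31) and an estimated correlation (-0.31, range 0.00790 to 0.597), and its median was -0.39 to -0.23 without 1 array and -0.19 with repaired normexp. The estimated correlation was -0.0554 for the cardiac list and 0.000739 for the myeloid list, both below the preset 0.01, and 0.474 for the p53 list. Correlation among members therefore does not account for the cardiac and myeloid losses in that test. That form of camera takes its p-values on the 3 residual degrees of freedom, whereas the preset form uses many more. A call can therefore be lost there through the few arrays alone. The cause of the other myeloid losses was not tested. The fry test, which asks about change rather than a shift against other genes, passed the cardiac (0.000263), myeloid (0.00304) and p53 (0.0239) lists and also the targeted GATA (4.28e-05), retinoic acid (0.00364) and gastrula (0.0239) lists. Over the 20 fixed lists, and the 3 added lists (by unadjusted p) under all alternatives but the estimated correlation and fry, 367 results were unchanged in call, 11 lost and 7 gained a call. For named genes these were 1291, 151 and 36, with 3 reversed. Outside fry, the targeted GATA list gained its call with the replicate block (camera adjusted p = 0.00169) and default normexp (0.00790). The retinoic acid list gained it with repaired normexp (median -0.15, camera adjusted p = 0.0195), and 1 added list with default normexp.

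With the replicate block 937 genes were higher and 847 lower (80.0% of the calls kept), and six1a, mmp9, tp63 and cyp26a1 lost their calls. Same-numbered arrays deviated together only weakly (r = 0.123 and 0.200 for 2 pairs), so the numbers are not taken to pair the samples. The slide block was not run, since each slide held 1 group. Signal near background limits folds to bounds for genes such as nkx2.5.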

Other observations

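The 3 gene lists in this part, the genes named from them and the muscle test of embryo stage were chosen after seeing the data, so the lists are not independent evidence of direction. Most measured genes of plasma proteins, coagulation and complement rose in the gata5/6 morpholino embryos. Of 42 measured, 30 rose, 5 fell and 7 did not pass, with a median log2 change of 1.28 (1.02 with 3 members at their bounds, 0.68 and 0.75 with default and repaired normexp, camera p = 1.33e-11, adjusted over the 3 lists 4.00e-11, adjusted p = 0.0704 with an estimated correlation, so that call is then lost). The fibrinogen chain genes fga (3.37), fgb (2.92) and fgg (2.05), the coagulation factor genes f7 (3.77) and f2 (0.90), the vitronectin gene vtnb (3.26) and the complement regulator gene cfh (2.27) rose, at adjusted p of 4.11e-05 to 0.00268. The 5 that fell were mbl2 (-0.75), f3a (-0.37) and the apolipoprotein genes apoa1a (-0.97, adjusted p = 0.00137), apobb.1 (-0.42, adjusted p = 0.0280) and apoea (-3.73, adjusted p = 0.00166). Other apolipoprotein genes of the list did not fall, as apom (1.36, adjusted p = 0.00326) and apoa2 (0.68, adjusted p = 0.0479) rose and apoeb (-0.09, adjusted p = 0.581) did not pass. The transthyretin gene ttr (-0.91, adjusted p = 0.0582), well above background on 1 of the 2 gata5/6 morpholino arrays, did not pass and is also on the endoderm list.

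More genes of uptake and lipid handling at epithelial surfaces fell than rose. Of 16 measured, 9 fell, 2 rose and 5 did not pass, with a median of -1.71 (camera p = 8.29e-09, adjusted over the 3 lists 1.24e-08, adjusted p = 0.0487 with an estimated correlation). The median was -0.34 with no filter on dim probes, -0.98 with default and -0.60 with repaired normexp, and without the 5 genes noticed first 4 of 11 fell and 2 rose (median -0.34, camera adjusted p = 0.00516, adjusted p = 0.137 with an estimated correlation). These 11 still held apoa4a, already named among the largest falls. Beside cd36, the aminopeptidase genes anpepb.1 (-3.00) and enpep (-1.88), the fatty acid binding gene fabp2 (-2.68) and the cholesterol acyltransferase gene soat1 (-2.69) fell, at adjusted p of 0.000121 to 0.000294. The scavenger receptor gene scarb1 (0.61, adjusted p = 0.00729) and the meprin gene mep1ba (1.47, adjusted p = 0.00211) rose.

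Outside the 6 plasma protein genes noticed first, the other 36 also had a positive median of 0.909 (24 rose, 5 fell, camera adjusted p = 9.34e-07), although the adjusted p was 0.137 with an estimated correlation. These 36 still held ahsg1 and apoea, already named among the largest rises and falls. The list was chosen after seeing the data, so this is not a test on unseen genes. A later stage of the gata5/6 morpholino embryos was tested on muscle genes, whose RNA accumulates through somite stages. Of 19 measured, 5.26% rose, with pvalb2 3.68-fold higher, and the other 18 lay between -0.32 and 0.77. The muscle values were already known when this test was chosen, so it cannot exclude a later stage. A clutch or labelling difference stays open, since each slide held 1 group.

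For the lower p53 list, the values argue against array scaling as the whole cause, since the median nearest to 0 under quantile normalization, default normexp and the authors' values was -0.62. A difference in general stress and interferon response between the injected groups may account for it and stays open. Without isg15, 2 of 18 interferon-stimulated genes rose and 4 fell (median 0.01, camera adjusted p = 0.282), and with it 2 of 19 rose and 5 fell (median -0.06, camera adjusted p = 0.132). The median of the 19 was -0.30 with default normexp (unadjusted camera p of 0.00605) but -0.02 with repaired normexp (unadjusted camera p of 0.648). The bound written for this test, a p of 0.05 or more, was too weak to exclude the explanation, because members moved both ways, such as cxcl20, at least 4.51-fold higher after gata5/6 morpholino (adjusted p = 0.00341), and pkz, at least 2.02-fold higher in controls (adjusted p = 0.0145). Whether the control morpholino raised p53 genes was not tested, since uninjected embryos were not analysed here.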
